A study of Mus musculus with 8 samples.

How the data were processed

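Gene expression was measured by directional, ribosome-depleted RNA sequencing of total RNA from mouse bone marrow-derived macrophages. The cells were grown in M-CSF and came from IL10-/-RAG2-/- mice of the 129S6/SvEvTac strain, which carry disrupted Il10 and Rag2 genes. There were 4 groups of 2 libraries, 8 in all, and per the labels each group held cells from 2 independent macrophage pools. The groups were untreated cells, cells given LPS (a bacterial lipopolysaccharide that activates Toll-like receptor signalling) at 1 ng/mL for 195 min, cells given LPS together with IL-10 (an anti-inflammatory cytokine) at 1 ng/mL for the whole 195 min, and cells given LPS for 195 min with IL-10 for the last 30 min. The labels do not restate the IL-10 dose for the last group.

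The authors deposited 1 table of 11415 genes with 8 value columns, a mature mRNA signal and a pre-mRNA value for each group. Per the submitters' processing notes, Trim Galore, DESeq and genome build mm10 were used. Their versions, the aligner, the read counter, the gene annotation and the way reads were assigned to pre-mRNA are not given in the sources used here. Every deposited signal value of a column was a sum of whole multiples of 2 constants, with a largest relative error of 5.4e-15 and no second solution for any value. Each deposited value was therefore the mean of 2 libraries' read counts, each divided by its own size factor, and both libraries' counts were worked out from it for 100% of values. The same method, tested on 3 simulated columns of 8000 genes, returned 100% of the counts. Median-of-ratios size factors computed again from the recovered reads matched the deposited scaling to within 4.2e-06 on the log2 scale.

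The columns carry no replicate number, so the library with the larger size factor of each group is called library A and the other library B, separately for each measure. Library A of the mRNA measure and library A of the pre-mRNA measure need not come from the same culture, nor need the libraries A of different groups come from the same pool. The recovered libraries held 21412968 to 53172133 mRNA reads and 8661271 to 31508394 pre-mRNA reads over the genes of the table. The smallest count in either LPS mRNA library was 11, so genes with fewer LPS mRNA reads are missing from the table, and a gene that LPS silenced fully could not be seen. Recovering libraries from pooled means is a step beyond the group means as deposited. All p-values rest on it, and they measure the spread between these libraries, part of which may be technical.

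The planned test, a quasi-likelihood count test, was for deposited counts and was not used, because no column holds counts. The fallback fixed for normalized values was used instead. Values were normalized reads on the log2(value + 1) scale, which understates the change of low genes. They were fitted with limma-trend 3.58.1 in R 4.3.3, all 8 libraries of a measure in one fit with the group as the only term, for genes with a mean of at least 1. That left 11415 genes for mRNA and 11131 for pre-mRNA. The threshold was a Benjamini-Hochberg adjusted p under 0.05 within each comparison, and errors are standard errors of the log2 change with n = 2 libraries per group. The spread behind an error is estimated over all groups of the fit and moderated across genes, so it is not that of the compared groups alone. "Rose" and "fell" are used for values past this threshold. The test, the comparisons, the 20 pathway lists, the cell type markers, the named genes and the first set of alternatives were chosen before the data were examined.

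The named genes were, per comparison and measure, the 5 largest rises and 5 largest falls past the threshold with a mean of at least 5 and no overlap between the groups' libraries, up to 2 members of each list with the smallest adjusted p, and 13 fixed genes. Predicted genes were skipped in the first part. The 13 fixed genes were Tnf, Il6, Il1b, Il12b, Cxcl10, Ifit1, Nos2, Ptgs2, Socs3, Bcl3, Nfil3, Il1rn and Il4ra. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 160 tests (20 lists, 4 comparisons, 2 measures), and again with an estimated correlation and with fry. Counts adjusted over the list alone are given beside those over all genes where the 2 differ. Folds against a group with no reads are lower bounds against a floor of 3 reads over the group, and 95% intervals of folds with few reads are exact binomial. Both cover counting error only.

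Overlaps between comparisons that share the LPS libraries were set against n1 × n2 / N for independent lists and against 100 simulated sets with unchanged IL-10 groups. The difference between pre-mRNA and mRNA changes was tested in one limma fit of both measures. That comparison was added after the values were seen, and it treats the measures as independent although they come from the same RNA. A simulation with known changes in IL-10 throughout against LPS recovered 7.58%, 64.2% and 89.6% of changes of 1, 2 and 3 log2 units for mRNA among 11415 genes. For pre-mRNA it recovered 4.55%, 59.7% and 80.6% among 11131 genes. Unchanged genes were called in 3 of 11215 and 6 of 10931 cases. The simulation drew every gene and library independently with the fitted spread. It therefore does not show how the test performs with pool differences shared across groups or with correlated genes.

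Alternatives covered the scaling of libraries (total counts, TMM and recomputed median-of-ratios factors), limma-voom on the recovered reads, filters on low values, pseudocounts of 0.1 and 5, a fold limit, fits of the compared groups only, leaving out each library and a block for pools matched from the data. A planned Wald test on counts was not run. Of the 11415 gene symbols, 10889 matched the GRCm38.p6 annotation (the mm10 assembly) by symbol and 494 by an older symbol, and 32 had no match. Coordinates come from that annotation. Recovery and figures used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.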

Results

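Mature and precursor transcripts were measured in macrophages grown from bone marrow and given LPS with or without IL-10, in 4 groups of 2 libraries: untreated, LPS for 195 min, LPS with IL-10 for the same 195 min (IL-10 throughout) and LPS with IL-10 for the last 30 min (late IL-10). Reads over the 11415 genes of the table came to 38368730 and 21412968 per library for untreated mRNA, 38369836 and 34389726 for LPS, 43679095 and 31822644 for IL-10 throughout, and 53172133 and 41663415 for late IL-10. Pre-mRNA reads came to 25462969 and 8661271, 25801556 and 14946179, 26272775 and 15414715, and 31508394 and 18866631 in the same order. The 2 libraries of a group correlated at 0.955 to 0.968 across genes on the log2 scale, where genes are not independent replicates. All changes are on the log2 scale of normalized reads + 1, with limma's standard error and Benjamini-Hochberg adjusted p. Each group had 2 libraries, and the spread behind an error was shared over all 4 groups.

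All groups carried the same disrupted Il10 and Rag2 genes, so no comparison tested those genotypes. Reads were nevertheless assigned to both genes. Il10 mRNA had 229.5 and 144 normalized reads in the untreated libraries, 524.5 and 3171 with LPS, 5212 and 923.4 with IL-10 throughout, and 6199 and 1556 with late IL-10. Rag2 mRNA had 82.69 and 57.1, 43.28 and 60.23, 76.85 and 55.26, and 68.27 and 38.79 in the same order. Il10 pre-mRNA had 228 and 292.9 untreated, 2979 and 938 with LPS, 3868 and 1316 with IL-10 throughout, and 7401 and 2957 with late IL-10. Rag2 pre-mRNA had 95.88 and 85.97, 30.55 and 26.99, 67.85 and 84.14, and 28.26 and 61.72. The table does not show which part of each gene these reads covered, so they do not check the deletions.

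The comparison of LPS with untreated cells asked what 195 min of LPS changed. Il12b, which encodes the shared subunit of IL-12 and IL-23 (mm10 chromosome 11, 44400063 to 44414677), had a mean of 1.903 normalized mRNA reads untreated and 47210 with LPS, a log2 change of 13.90 ± 0.56 (SE, n = 2 per group, adjusted p = 2.5e-05). Tnf (chromosome 17, 35199367 to 35202007) rose by 8.90 ± 0.19, from 452.7 to 215800 (adjusted p = 3.2e-06). Il6 (chromosome 5, 30013114 to 30019975) had 1 read over both untreated libraries and 18440 with LPS, a ratio of 25400 with a 95% counting interval of 4550 to 1000000. Cxcl11, annotated as a transcribed pseudogene in this assembly, had no untreated reads and was at least 3930-fold higher with LPS. Il1a rose by 12.85 ± 0.93, Il1b by 10.36 ± 0.59, Irg1 (the itaconate-producing enzyme) by 10.69 ± 0.30 and Ptgs2 (an inducible cyclooxygenase) by 10.41 ± 0.44. Nos2, inducible nitric oxide synthase, had 3 untreated reads and 16050 with LPS, a ratio of 7360 with a counting interval of 2520 to 35700. Among the largest falls were Bmf, a pro-apoptotic BCL2-family gene (-6.45 ± 0.59), the cannabinoid receptor Cnr2 (-6.14 ± 1.02), the chemokine receptor Cxcr4 (-6.09 ± 0.84) and Zfp395 (-5.45 ± 0.30). Pparg, a lipid-activated nuclear receptor, fell by 2.62 on the log2 scale (SE 0.31).

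Whole groups of genes moved with LPS. All 42 interferon-stimulated genes rose (median 5.73, list test adjusted p = 2.7e-19, and adjusted p = 0.39 with an estimated correlation), among them Gbp5 (9.65 ± 0.66), Ifit1 (9.57 ± 0.91) and Oasl1 (9.19 ± 0.70). The 2 libraries of each LPS-treated group stood apart in this list: its median differed between them by 1.35 with LPS, 1.43 with IL-10 throughout and 1.29 with late IL-10, with all 42 members higher in the same library, against 0.218 between the untreated libraries. All 18 chemokines rose (median 9.03, adjusted p = 3.7e-14, and adjusted p = 0.28 with an estimated correlation), with Cxcl10 at 11.48 ± 0.53 and Cxcl1 at 10.15 ± 0.26. Of 22 inflammatory cytokines 20 rose, 21 when adjusted over the list alone (median 8.23, adjusted p = 3.5e-14, and adjusted p = 0.28 with an estimated correlation). The libraries also stood apart in these 2 lists, by 0.616 to 0.999 for chemokines and 0.638 to 1.18 for cytokines in the LPS-treated groups against 0 and 0.182 untreated. The medians of both lists were the same with genes of an unread group at their bound. All 27 NF-κB pathway and feedback genes rose (median 3.88, adjusted p = 4.7e-19, and adjusted p = 0.28 with an estimated correlation), including the adhesion molecule Icam1 (6.60 ± 0.24) and the inhibitor Nfkbia (4.46 ± 0.19). Of 17 genes of MHC class I presentation 12 rose, including the peptide transporter Tap1 (3.47 ± 0.54), and of 19 glycolysis genes 11 rose, including the transporter Slc2a6 (4.53 ± 0.26). Of 21 cholesterol synthesis genes 12 rose and 1 fell (13 rose adjusted over the list alone), with Insig1 at 2.01 ± 0.16 and Srebf2 at 2.02 ± 0.18. These 3 lists had adjusted p = 3.3e-05, 4.4e-05 and 1.1e-04, and adjusted p = 0.49, 0.39 and 0.35 with an estimated correlation.

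Members of other lists also moved. Of 28 Toll-like receptor and adaptor genes 15 rose and 2 fell (19 and 2 adjusted over the list alone), of 12 costimulatory and checkpoint ligands 8 rose, and of 14 nitric oxide and prostanoid genes 8 rose and 2 fell (9 and 2 adjusted over the list alone). Of 24 IL-10/STAT3 response genes 11 rose and 3 fell, with the cytokine signalling inhibitor Socs3 at 8.76 ± 0.28. Of 23 immediate-early genes 10 rose and 1 fell (10 and 2 adjusted over the list alone), and of 18 MAPK phosphatases and RNA decay factors 7 rose and 2 fell (8 and 3). Those 6 lists passed the list test with adjusted p from 0.00037 to 0.03, and none did with an estimated correlation (adjusted p from 0.28 to 0.64). The inflammasome genes (7 rose and 3 fell of 14, with Nlrp3 at 4.94 ± 0.20), macrophage identity genes (5 rose and 4 fell of 26), cholesterol efflux genes (2 rose and 4 fell of 14), cell cycle genes (3 rose and 2 fell of 28, 3 and 1 adjusted over the list alone), lysosomal genes (3 fell of 26, 1 adjusted over the list alone), oxidative phosphorylation genes (2 rose and 1 fell of 27, 0 and 0 adjusted over the list alone) and MHC class II genes (1 rose of 9, 0 adjusted over the list alone) did not pass it.

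By mRNA 2193 genes rose and 1887 fell of 11415 with LPS, 1773 and 1494 of them by at least 2-fold on the fitted scale. By pre-mRNA 2484 rose and 2418 fell of 11131. These changes are relative to the median gene: scaling to total reads shifted all LPS changes by -0.75 (mRNA) and -0.92 (pre-mRNA), and then 1203 rose and 4497 fell by mRNA (21.1% rising in place of 53.8%) and 1238 rose and 4681 fell by pre-mRNA (20.9% in place of 50.7%). The 4080 mRNA calls became 2443 without untreated library A, 2584 without untreated library B and 1860 without LPS library B, and the 4902 pre-mRNA calls became 3196 and 3146 without untreated library A or B.

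By pre-mRNA, which follows ongoing transcription more closely than mature mRNA, LPS also raised the inflammatory lists and lowered lysosomal genes. All 42 interferon-stimulated genes, 27 NF-κB genes and 17 genes of MHC class I presentation rose, with 16 of 17 chemokines and 18 of 21 cytokines (19 adjusted over the list alone). In that order the list tests gave adjusted p = 9.7e-22, 1.7e-15, 1.5e-08, 8.8e-12 and 5.3e-10, and adjusted p = 0.35, 0.28, 0.35, 0.28 and 0.28 with an estimated correlation. Ccl5 rose by 13.66 ± 1.03 and the formyl peptide receptor Fpr2 by 11.58 ± 0.20. Of 26 lysosomal genes 15 fell and 2 rose (median -1.57, adjusted p = 0.00039, and adjusted p = 0.35 with an estimated correlation), including the protease gene Lgmn (-4.80 ± 0.19) and Gpnmb (-3.77 ± 0.36). Trem2, a lipid-sensing receptor of macrophages, fell by 6.01 on the log2 scale (SE 0.49), Pparg fell by 4.35 (SE 0.27), and Bmf had the largest fall (-8.28 ± 1.09). Of 19 glycolysis genes 15 rose by pre-mRNA, and of 21 cholesterol synthesis genes 15 rose and 1 fell (16 and 1 adjusted over the list alone). These 2 lists had adjusted p = 1.3e-07 and 0.00028, and adjusted p = 0.28 and 0.40 with an estimated correlation.

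Markers of other cell types were measured beside these changes. The table held 7 of 12 listed neutrophil and granule genes, 5 of 10 dendritic cell genes, 3 of 9 T cell genes and 1 of 9 stromal genes. Its smallest count in either LPS mRNA library was 11, so a low marker is in it only with reads under LPS. That selection favours rises with LPS. With LPS, 5 of 7 neutrophil and granule genes rose by mRNA (S100a9 by 3.66, Ngp by 2.86, Camp by 4.24, Ltf by 3.18 and Mpo by 2.63), with no library above 373.7 normalized reads for any of them. Of 5 dendritic cell genes 4 rose (Zbtb46, Xcr1, Itgax and Ccr7). Lck rose and Cd28 fell of 3 T cell genes, the innate lymphoid marker Il7r fell, and Cdh5 (endothelial), Pf4 (megakaryocyte) and Pdgfra (stromal) rose. The single B cell and mast cell genes in the table did not pass the threshold, and none of the 19 genes on the RNA quality list was in it. Of the 24 marker genes tested by mRNA, limma called 0 in the comparisons with IL-10. At an unadjusted p under 0.05, 1 was higher and 6 lower with IL-10 throughout, 0 differed with late IL-10, and 4 were lower with IL-10 throughout than with late IL-10, and limma-voom called 0 in each. By pre-mRNA limma called 3 of 22 marker genes with IL-10 throughout: the neutrophil gene Mmp8 rose by 3.45 ± 0.47, and the dendritic cell gene Itgax (-2.49 ± 0.30) and the endothelial gene Kdr (-2.67 ± 0.60) fell. Between the schedules Mmp8 was higher with IL-10 throughout (3.16 ± 0.47), and Itgax (-2.07 ± 0.30), Batf3 (-2.61 ± 0.50) and Lck (-2.97 ± 0.51) were lower. With late IL-10 limma called 0 of the 22 by pre-mRNA, with 1 higher at an unadjusted p under 0.05 and 0 by limma-voom.

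**Figure D1:**
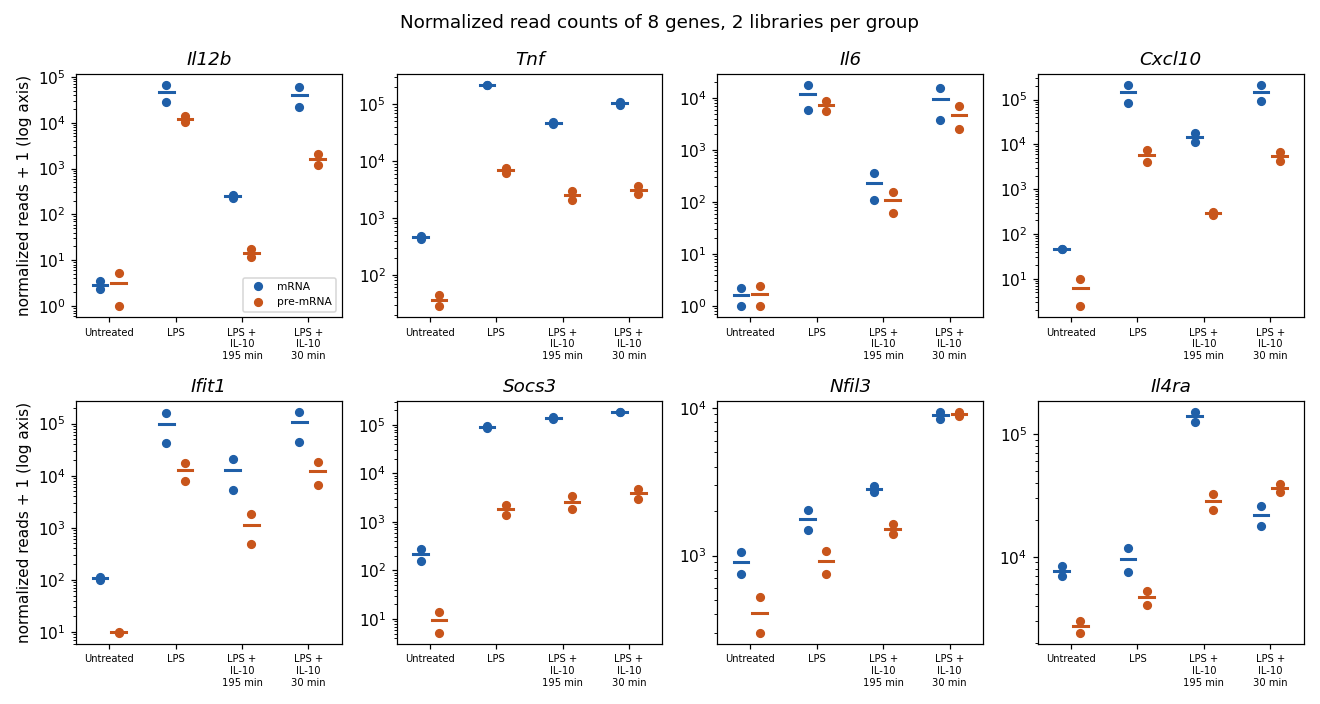
Normalized reads + 1 (log axis) of 8 genes in the 4 groups, with mRNA in blue and pre-mRNA in orange, points for the 2 libraries and a bar for their mean. Il12b mRNA averaged 47210 with LPS, 248.1 with IL-10 throughout and 41000 with late IL-10, while its pre-mRNA averaged 12090, 13.51 and 1630.

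The comparison of IL-10 throughout with LPS alone asked which LPS-driven changes IL-10 altered. Il12b mRNA fell by 7.45 on the log2 scale (SE 0.56, adjusted p = 0.0044), from 47210 to 248.1 normalized reads, and Tnf mRNA fell by 2.20 (SE 0.19, adjusted p = 0.0057). Csf2, which encodes GM-CSF, fell from 967.8 to 8.634 (-6.55 ± 0.73), Il6 from 11840 to 234.4 (-5.69 ± 0.91), and the chemokine genes Ccl17 (-5.57 ± 0.65), Cxcl1 (-3.52 ± 0.26), Cxcl10 (-3.23 ± 0.53) and Cxcl2 (-3.02 ± 0.35) also fell. Rises were led by Steap4, a metalloreductase gene on chromosome 5 (7960472 to 7982213), from 33.64 to 5261 (7.48 ± 0.61, adjusted p = 0.0057). The receptor gene Gpr35 (5.77 ± 0.53), the lymphocyte-activation receptor Slamf1 (5.26 ± 0.88), haptoglobin (Hp, 4.92 ± 0.68) and the metalloproteinase inhibitor Timp1 (4.69 ± 0.70) rose too. Il4ra, the IL-4 receptor alpha chain (chromosome 7, 125552271 to 125579474), rose by 3.89 ± 0.31 to a mean of 139900, and Bcl6, a transcriptional repressor, rose by 2.95 ± 0.22. Pfkfb3, whose product promotes glycolysis, rose by 4.22 ± 0.47, and the MAPK phosphatase gene Dusp1 by 2.85 ± 0.39.

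Among the fixed genes, Il1b (-1.68 ± 0.59, adjusted p = 0.24), Ifit1 (-2.95 ± 0.91, adjusted p = 0.19), Nos2 (1.52 ± 0.48, adjusted p = 0.19), Bcl3 (1.89 ± 0.40, adjusted p = 0.072), Il1rn (2.15 ± 0.74, adjusted p = 0.23), Nfil3 (0.69 ± 0.24, adjusted p = 0.24), Socs3 (0.62 ± 0.28, adjusted p = 0.38) and Ptgs2 (0.20 ± 0.44, adjusted p = 0.92) did not pass the threshold by mRNA. Of 22 cytokines 11 fell (14 adjusted over the list alone), with a median of -2.20, and of 18 chemokines 7 fell (16 adjusted over the list alone), with a median of -3.21. The 2 libraries differed in the median of cytokines by 1.18 with LPS and 0.638 with IL-10 throughout, and of chemokines by 0.616 and 0.645. Their list tests gave adjusted p = 2.9e-12 and 1.3e-15, and adjusted p = 0.32 and 0.28 with an estimated correlation. Of 27 NF-κB genes Icam1 alone fell (-1.54 ± 0.24), with 13 adjusted over the list alone and a median of -0.77 (adjusted p = 1.6e-07, and adjusted p = 0.35 with an estimated correlation). Of 42 interferon-stimulated genes limma called 0 by mRNA over all genes, 32 were lower at an unadjusted p under 0.05, limma-voom called 0, and 30 fell when adjusted over the list alone. The fit has no pool term, so a difference between the macrophage pools counts as error in it. A block of pools was matched from the same values, so its p-values can be too small. It raised the mRNA calls of this comparison from 256 to 1743 and called 27 of the 42 lower, Ifit1 among them. The median of this list was -1.77 (adjusted p = 5.3e-17, and adjusted p = 0.40 with an estimated correlation). Of 24 IL-10/STAT3 response genes 8 rose, and 13 rose and 2 fell when adjusted over the list alone (median 0.90, adjusted p = 1.2e-08, and adjusted p = 0.28 with an estimated correlation). Of 28 Toll-like receptor and adaptor genes 3 fell, including Tlr9 (-2.04 ± 0.28) and Ticam2 (-1.84 ± 0.25).

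Inflammatory lists fell by pre-mRNA too. Il12b pre-mRNA fell by 9.71 on the log2 scale (SE 0.72, adjusted p = 0.0021), from 12090 to 13.51 normalized reads, Il6 fell by 6.16 (SE 0.66), and the chemokine gene Ccl22 fell by 6.20 (SE 0.49). The chemokine gene Cxcl9 had 1 read with IL-10 throughout and 299 with LPS, a ratio of 429 with a counting interval of 76.4 to 17000. Tslp had no pre-mRNA reads with IL-10 throughout and was at least 60.2-fold lower. Of 42 interferon-stimulated genes 26 fell (41 adjusted over the list alone), including Ifit1 (-3.65 ± 0.71), Oasl1 (-2.76 ± 0.36) and the transcription factor Irf1 (-2.19 ± 0.30). The list median was -2.49 (adjusted p = 5.1e-22, and adjusted p = 0.35 with an estimated correlation), and the 2 libraries of these groups differed in it by 0.974 (LPS) and 1.41 (IL-10 throughout). Of 17 chemokines 11 fell (17 adjusted over the list alone), of 21 cytokines 10 fell (14 fell and 1 rose), of 17 MHC class I presentation genes 6 fell (16), and of 12 costimulatory and checkpoint ligands 4 fell and Slamf1 rose (9 fell and 1 rose). Those 4 lists had adjusted p = 3.3e-13, 2.5e-08, 8.9e-10 and 1.2e-04, and adjusted p = 0.28, 0.28, 0.35 and 0.35 with an estimated correlation. Of 21 cholesterol synthesis genes 3 rose (9 adjusted over the list alone), among them Lss (2.11 ± 0.25) and Fdps (1.76 ± 0.35), with a median of 0.88 (adjusted p = 5.8e-07, and adjusted p = 0.35 with an estimated correlation). Hp rose by 6.29 ± 0.79, Creg2 by 6.12 ± 0.54, Neurl2 by 5.11 ± 0.43, Pfkfb3 by 3.86 ± 0.46, Il4ra by 2.60 ± 0.32 and Itgam, which encodes the integrin CD11b, by 2.60 ± 0.25. In the annotation Neurl2 (chromosome 2, 164830730 to 164833596) overlaps Ctsa (164832872 to 164841032), and how reads in the overlap were assigned is not known.

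With IL-10 throughout, 136 genes rose and 120 fell by mRNA and 272 rose and 474 fell by pre-mRNA. At an unadjusted p under 0.05 the mRNA split turned, with 716 higher and 955 lower, and by pre-mRNA 1053 were higher and 1515 lower. Scaling to total reads shifted these changes by 0.26 and 0.46 and gave 174 rises and 101 falls by mRNA (63.3% rising in place of 53.1%) and 385 rises and 348 falls by pre-mRNA (52.5% in place of 36.5%). The 256 mRNA calls became 85 without LPS library A, 43 without LPS library B, 60 without library A of IL-10 throughout and 51 without its library B. The 746 pre-mRNA calls became 161 (89 rises and 72 falls) and 1152 without LPS library A or B, 161 and 62 without library A or B of IL-10 throughout, and 436 and 446 without untreated library A or B. Of 31 named genes past the threshold by mRNA, 7 stayed past it whichever library was left out (Bcl6, Cxcl1, Gpr35, Il12b, Il4ra, Steap4 and Tnf), and of 44 by pre-mRNA 13 did (Ccl22, Creg2, Csf2, Cxcl9, Gpr35, Il12b, Il6, Itgam, Neurl2, Pfkfb3, Slamf1, Tnfsf15 and Tslp).

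Falls with IL-10 throughout lay mostly among genes that LPS had raised. Of the 120 genes lower by mRNA, 107 (89.2%) had risen with LPS, against 23.1 for independent lists. Of the 474 genes lower by pre-mRNA, 375 (79.1%) had risen with LPS, against 106 for independent lists. In 100 simulations without an IL-10 effect the median overlap was 0 (highest 1) by each measure. Unchanged groups gave almost no falls, so this does not show what overlap shared LPS libraries would give among so many falls. The LPS and IL-10 comparisons use the same 2 LPS libraries, so part of the excess over independent lists may come from the shared controls. The covariance of the LPS and IL-10 changes across genes was -0.675 by mRNA against -0.0986 simulated, and -1.16 against -0.132 by pre-mRNA. Of the 107 genes, 57 still lay above the untreated level, 8 lay below it and 42 did not differ past the threshold, with a median of 1.37 above untreated in place of 3.83 with LPS alone. Of the 375 genes, 174 lay above, 10 below and 191 did not pass, with a median of 1.10 in place of 3.22. The 107 became 27 and 15 without LPS library A or B, 25 and 18 without library A or B of IL-10 throughout, and 67 without library A of late IL-10. The 375 became 63 and 612, 102 and 26 without the same 4 libraries, and 207 and 215 without untreated library A or B.

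Many LPS-raised genes were above the untreated level under both schedules. Of the 2193 genes raised by mRNA, 1369 (62.4%) were above untreated with IL-10 throughout and 2084 (95%) with late IL-10. Of the 2484 raised by pre-mRNA, 1340 (53.9%) and 2097 (84.4%) were. Independent lists would share 312 and 423 by mRNA and 350 and 544 by pre-mRNA. In 100 simulations every group, LPS included, was set to the untreated level and the shared count was 0. That result was fixed in advance, so it sets no level for the counts seen. All these comparisons use the same 2 untreated libraries, so part of the excess may come from the shared controls. By mRNA, the 1369 became 849 of 1474 (57.6%) and 907 of 1517 (59.8%) without untreated library A or B and 744 of 2010 (37%) without library A of IL-10 throughout. The 2084 became 1386 of 1474 (94%) without untreated library A, 1151 of 1155 (99.7%) without LPS library B and 1166 of 2071 (56.3%) without library A of late IL-10. By pre-mRNA, the 1340 became 790 of 1709 (46.2%) and 838 of 1644 (51%) without untreated library A or B and 673 of 2229 (30.2%) without library A of IL-10 throughout. The 2097 became 1380 of 1644 (83.9%) without untreated library B and 1306 of 2334 (56%) without library A of late IL-10. With total-read scaling fewer genes rose with LPS, and the shares were 826 (68.7%) and 1152 (95.8%) of 1203 by mRNA and 797 (64.4%) and 1079 (87.2%) of 1238 by pre-mRNA.

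The comparison of late IL-10 with LPS alone asked what IL-10 changed within 30 min in cells already responding to LPS. The changes seen were mostly rises of pre-mRNA. Steap4 pre-mRNA rose from 8.4 to 1614 normalized reads (7.75 ± 0.75, adjusted p = 0.004). The receptor gene Cd244 rose by 5.12 ± 0.50, Sema6b by 5.38 ± 0.77 and Timp1 by 5.32 ± 0.71. Dusp1 rose by 4.37 ± 0.41, the immunoglobulin receptor gene Fcgr3 by 3.43 ± 0.31, Slamf1 by 3.56 ± 0.49 and Pfkfb3 by 3.11 ± 0.46. Nfil3, a transcriptional repressor gene (chromosome 13, 52967209 to 52982878), rose from 912.7 to 9073 (3.34 ± 0.31, adjusted p = 0.004), Il4ra by 2.98 ± 0.32 and Bcl3, an atypical IκB family gene, by 2.59 ± 0.30. The 7 falls included the Notch ligand gene Jag1 (-1.84 ± 0.20), Fgd3 (-2.06 ± 0.30), Abhd17c (-1.82 ± 0.23), Cdc42ep4 (-1.71 ± 0.22) and Tmem123 (-1.44 ± 0.24).

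The fixed inflammatory genes did not pass the threshold after 30 min in the fit without a block. By pre-mRNA the block of matched pools called 2 of 21 cytokines lower and 1 higher. It called 1 of 17 chemokines and 1 of 27 NF-κB genes lower. Il12b pre-mRNA averaged 1630 with late IL-10 against 12090 with LPS (-2.93 ± 0.72, adjusted p = 0.16), and Tnf pre-mRNA 3132 against 6948 (-1.16 ± 0.30, adjusted p = 0.19). Il6 (-0.78 ± 0.66), Il1b (-0.22 ± 0.46) and Ifit1 (-0.12 ± 0.71) pre-mRNA had adjusted p = 1. Nos2 (1.05 ± 0.56, adjusted p = 0.87), Socs3 (1.08 ± 0.53, adjusted p = 0.79), Il1rn (2.30 ± 0.55, adjusted p = 0.15) and Ptgs2 (0.45 ± 0.45, adjusted p = 1) did not pass either. Cxcl10 pre-mRNA had -0.02 ± 0.63 (adjusted p = 1), which became 0.0027 with total-read scaling. Of 42 interferon-stimulated genes limma called 0 by pre-mRNA, with 0 at an unadjusted p under 0.05 and 0 by limma-voom, and the list median was 0.0063 (mean -0.0098).

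Of 24 IL-10/STAT3 response genes, 8 rose by pre-mRNA after 30 min (12 adjusted over the list alone), with a median of 1.36 (adjusted p = 5.2e-17, and adjusted p = 0.20 with an estimated correlation). By mRNA limma called 0 of the 24 over all genes, 10 were higher at an unadjusted p under 0.05, limma-voom called 0, and 9 rose when adjusted over the list alone (Socs3, Nfil3, Etv3, Sbno2, Il4ra, Ddit4, Bcl6, Tnip3 and Gadd45g). The mRNA median was 0.65 (adjusted p = 3.2e-34, and adjusted p = 0.066 with an estimated correlation), with Nfil3 at 2.35 ± 0.24 (adjusted p = 0.13), Il4ra at 1.19 ± 0.31 and Socs3 at 1.02 ± 0.28 (both adjusted p = 1 over all genes). Of 18 MAPK phosphatases and RNA decay factors Dusp1 alone rose by pre-mRNA (4 rose and 1 fell adjusted over the list alone, adjusted p = 0.022, and adjusted p = 0.35 with an estimated correlation). By mRNA limma called 0 of them, with 3 higher at an unadjusted p under 0.05, 0 by limma-voom and 2 higher adjusted over the list alone, while the list passed its test (adjusted p = 3.7e-07, and adjusted p = 0.28 with an estimated correlation). The chemokine, NF-κB and Toll-like receptor lists were called lower by pre-mRNA with medians of -0.20, -0.22 and -0.25 (adjusted p = 0.0079, 0.026 and 0.029), and adjusted p = 0.48, 0.64 and 0.49 with an estimated correlation. By mRNA the cytokine list was called lower with a median of -0.14 (adjusted p = 0.029, 0.28 without LPS library B and in the other direction, and 0.69 with an estimated correlation), and the macrophage identity list higher with a median of 0.06 (adjusted p = 0.011, and adjusted p = 0.28 with an estimated correlation).

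By pre-mRNA 109 genes rose and 7 fell of 11131 with late IL-10. By mRNA limma called 0 of 11415, with 92 higher and 15 lower at an unadjusted p under 0.05 and a smallest adjusted p of 0.124, and limma-voom called 0. All 109 genes that rose by pre-mRNA had an mRNA change above 0, with a median of 0.55 against 2.37 by pre-mRNA. The 109 were chosen by their pre-mRNA rise, which can inflate the 2.37. Both measures come from the same RNA, so part of the shared direction may be built in. With IL-10 throughout the mRNA change of the 109 had a median of 1.81, and 58 of them were called higher, against 136 of all 11415 genes. That comparison uses the same LPS cultures, so part of the excess may come from the shared controls. The 116 pre-mRNA calls became 77 and 73 without LPS library A or B and 34 and 29 without library A or B of late IL-10. Of 18 named genes past the threshold by pre-mRNA, 6 stayed past it whichever library was left out, among them Cd244, Dusp1, Fcgr3, Nfil3 and Steap4.

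Of the 109 late pre-mRNA rises, 72 also rose by pre-mRNA with IL-10 throughout, against 2.66 for independent lists, and 0 fell with IL-10 throughout by limma. Simulated unchanged groups shared at most 1, but they gave almost no rises to share, so this does not measure the part due to shared libraries. Of the 7 late falls, 3 also fell with IL-10 throughout, against 0.298. The schedules share their LPS libraries, so part of the excess may come from the shared controls. The covariance of the 2 schedules' changes was 0.266 by pre-mRNA against 0.128 simulated, a difference of 0.138, with a correlation across genes of 0.44 (0.51 simulated). By mRNA it was 0.0719 against 0.0990, a difference of -0.027, with a correlation of 0.35 (0.50 simulated), and the covariance was -0.0115 without library B of late IL-10 and 0.276 without LPS library A. The simulation varied each library independently by the full spread within groups. If the same pools run through all groups, part of that spread cancels in the changes, and the simulated values are too high. These differences therefore do not show whether the schedules agreed more or less than unchanged groups would. Of the 109 late rises 52 had fallen with LPS (23.7 for independent lists) and 20 had risen with it (24.3). The LPS libraries enter the LPS and late IL-10 changes with opposite sign, so part of the 52 may come from the shared controls. By pre-mRNA the covariance of these changes was -0.191 against -0.129 simulated. The 72 shared rises became 39 without LPS library A, 26 and 20 without library A or B of IL-10 throughout, and 28 and 24 without library A or B of late IL-10.

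**Figure D2:**
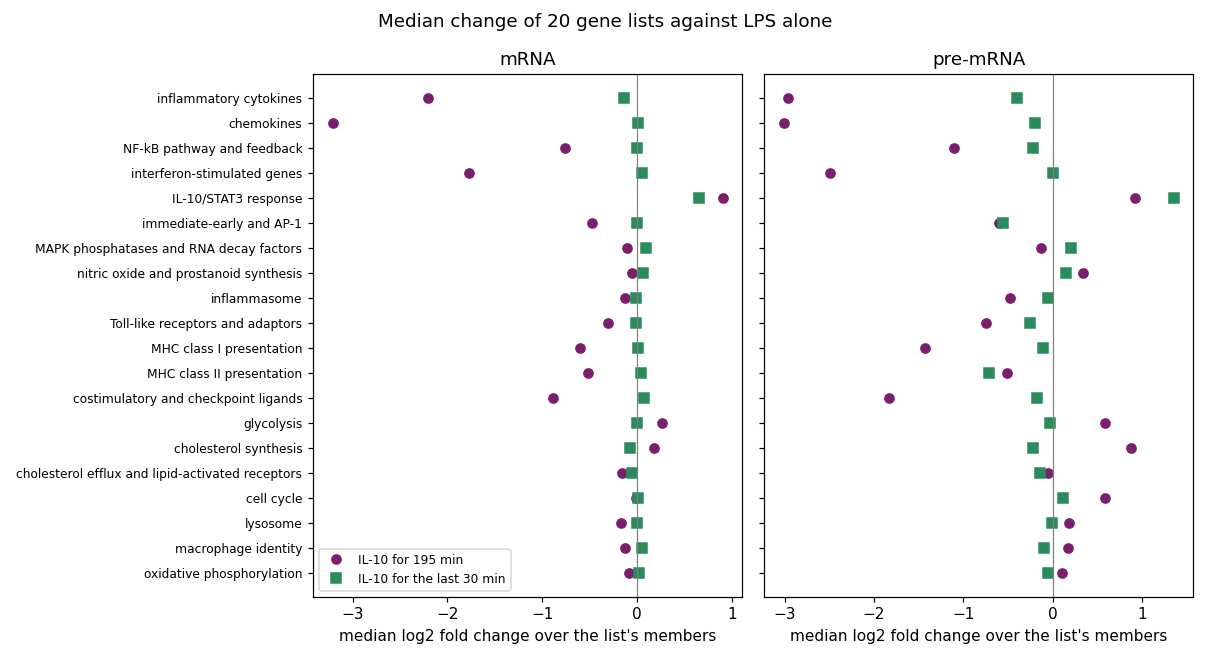
Median log2 change against LPS alone of the 20 gene lists, by mRNA and by pre-mRNA in separate panels, for IL-10 throughout (purple circles) and late IL-10 (green squares). Interferon-stimulated genes had a pre-mRNA median of -2.49 with IL-10 throughout and 0.0063 with late IL-10, and the IL-10/STAT3 response genes had 0.92 and 1.36.

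The direct comparison of the schedules asked where IL-10 throughout and late IL-10 differed. Il12b was lower with IL-10 throughout by both measures (-7.18 ± 0.56 by mRNA, adjusted p = 0.0084, and -6.78 ± 0.72 by pre-mRNA, adjusted p = 0.014). By mRNA, Ccl17 (-5.12 ± 0.65), Csf2 (-4.97 ± 0.73), Il12a (-4.48 ± 0.72), Il23a (-3.94 ± 0.49), Cxcl10 (-3.32 ± 0.53) and Cxcl1 (-2.75 ± 0.26) were also lower, and the claudin gene Cldn23 had 1 read against 179, a ratio of 172 with a counting interval of 30.5 to 6840. Higher with IL-10 throughout were Ggta1, which encodes a galactosyltransferase (3.72 ± 0.20, adjusted p = 0.0041), the deacetylase gene Hdac9 (4.21 ± 0.58), Mmp19 (3.21 ± 0.46), the fatty acid elongase gene Elovl6 (3.21 ± 0.40), March1, a ubiquitin ligase gene (3.09 ± 0.31), Il4ra (2.70 ± 0.31) and Bcl6 (2.06 ± 0.22). Nfil3 was lower with IL-10 throughout by mRNA (-1.65 ± 0.24, adjusted p = 0.035) and by pre-mRNA (-2.59 ± 0.31, adjusted p = 0.021). By pre-mRNA, Il6 (-5.38 ± 0.66), Cxcl10 (-4.24 ± 0.63), the STAT-induced inhibitor Cish (-3.69 ± 0.54) and Ifit1 (-3.53 ± 0.71) were lower, and Neurl2 (4.67 ± 0.43), Egln3, an oxygen-sensing hydroxylase gene (4.60 ± 0.49), Itgam (2.45 ± 0.25), Csf1r (2.06 ± 0.29) and Lss (2.07 ± 0.25) were higher. Tnf did not pass by mRNA (-1.14 ± 0.19, adjusted p = 0.051) or by pre-mRNA (-0.30 ± 0.30, adjusted p = 0.62, and 0.13 with total-read scaling).

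Of 42 interferon-stimulated genes 16 were lower by pre-mRNA with IL-10 throughout than with late IL-10, and 42 when adjusted over the list alone (median -2.51, adjusted p = 6.9e-24, and adjusted p = 0.35 with an estimated correlation). By mRNA limma called 0 of them over all genes, 32 were lower at an unadjusted p under 0.05, limma-voom called 0, and 32 were lower when adjusted over the list alone. The block of matched pools called 26 lower. Of 18 chemokines 5 were lower by mRNA (16 adjusted over the list alone, median -2.99), and of 22 cytokines 4 were (15 adjusted over the list alone, median -1.95). Both lists had adjusted p = 0.28 with an estimated correlation, against 3.6e-16 and 8.8e-14 at the preset one. Of 21 cholesterol synthesis genes 4 were higher by pre-mRNA (13 adjusted over the list alone, median 1.17, adjusted p = 3.9e-10, and adjusted p = 0.32 with an estimated correlation). The IL-10/STAT3 list was called higher by mRNA (median 0.48, adjusted p = 0.018) and lower by pre-mRNA (median -0.55, adjusted p = 0.011), and had adjusted p = 0.35 by each measure with an estimated correlation.

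Between the schedules, 59 genes were higher and 65 lower with IL-10 throughout by mRNA, and 84 higher and 245 lower by pre-mRNA, which became 142 and 207 with total-read scaling (40.7% higher in place of 25.5%, at a shift of 0.44). A fit of these 2 groups alone called 0 genes by mRNA, with 1382 at an unadjusted p under 0.05, and 19 by pre-mRNA. The 124 mRNA calls became 8 and 2 without library A or B of IL-10 throughout, 1 and 2 without library A or B of late IL-10, 55 and 54 without LPS library A or B, and 77 without untreated library B. The 329 pre-mRNA calls became 1 and 1, 1 and 33, and 554 and 599 without the same 6 libraries, and 103 and 104 without untreated library A or B. Ggta1 by mRNA was the 1 of 21 named genes that stayed past the threshold whichever library was left out, and 0 of 30 did by pre-mRNA.

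Some genes changed differently in pre-mRNA and mRNA, and the genes named here were chosen after their values were seen. With LPS the pre-mRNA change lay above the mRNA change for 18 genes and below it for 120, of 11131. Trem2 (-5.63 ± 0.58), the lysosomal genes Gm2a (-4.61 ± 0.37), Laptm5 (-4.25 ± 0.36) and Lgmn (-4.09), and the sialyltransferase gene St6gal1 (-4.36 ± 0.28, adjusted p = 4.9e-05) had pre-mRNA changes far below those of their mRNA. The complement gene C3 (3.08 ± 0.54), Bst2 (2.98 ± 0.44) and Fpr2 (2.62 ± 0.44) had the reverse. With late IL-10 the pre-mRNA change was the larger one for 15 genes and the smaller one for 0 by limma, where 385 genes differed at an unadjusted p under 0.05. Ggta1 pre-mRNA rose by 4.04 against 0.71 for its mRNA (difference 3.33 ± 0.29, adjusted p = 0.0011), and the metallothionein gene Mt1 (3.41 ± 0.38), Rab31 (3.11 ± 0.33), the properdin gene Cfp (2.99 ± 0.40), Fcgr3 (2.83 ± 0.44) and Slc9a3r1 (2.50 ± 0.25) had similar differences. With IL-10 throughout 6 genes lay above and 1 below, including Itgam (2.84 ± 0.32), Gm2a (3.38 ± 0.37) and Pltp (3.03 ± 0.37) above and Prr5l (-1.98 ± 0.29) below.

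Between the schedules the 2 measures differed for 55 genes, 17 above and 38 below. Ggta1 (-3.29 ± 0.29), Mt1 (-3.95 ± 0.38), Elovl6 (-4.40 ± 0.48), Mmp19 (-4.16, adjusted p = 0.01) and Il4ra (-3.08, adjusted p = 0.011) were higher with IL-10 throughout by mRNA relative to pre-mRNA. Across genes the changes of the 2 measures correlated at 0.90 with LPS, 0.79 with IL-10 throughout, 0.45 with late IL-10 and 0.62 between the schedules. Total-read scaling gave 88 calls with LPS, 9 with late IL-10 and 30 between the schedules in place of 138, 15 and 55. The 138 became 41 and 35 without untreated library A or B, 36 and 66 without LPS library A or B, and 72 and 78 without library A or B of IL-10 throughout. The 7 with IL-10 throughout became 0 without any 1 of the LPS libraries or its own, 3 and 3 without untreated library A or B, and 3 and 4 without library A or B of late IL-10. The 15 with late IL-10 became 8 and 3 without LPS library A or B, 5 and 5 without library A or B of IL-10 throughout, and 0 without either of its own. The 55 between the schedules became 3 and 8 without library A or B of IL-10 throughout and 0 without either library of late IL-10.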

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

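No tests of this part were chosen only after the result was seen, and the fits without 1 library were planned. Each of the following results stood out because the response to IL-10 differed between the schedules in a direct limma test of the difference. By mRNA 124 genes differed and by pre-mRNA 329, and neither count held without a library of either schedule. The 124 became 8 and 2 without library A or B of IL-10 throughout, 1 and 2 without library A or B of late IL-10, 55 and 54 without LPS library A or B and 77 without untreated library B. The 329 became 1 and 1, 1 and 33, and 554 and 599 without the same 6 libraries, and 103 and 104 without untreated library A or B. By mRNA the change with IL-10 throughout minus that with late IL-10 was 4.21 for Hdac9, 3.72 for Ggta1, -7.18 for Il12b and -5.79 for Cldn23, the last on 1 read against 179. By pre-mRNA it was 4.67 for Neurl2, 4.60 for Egln3, -6.78 for Il12b and -6.61 for Cxcl9, the last on 1 read against 330. Neurl2 overlaps Ctsa in the annotation, so its value may include reads of that gene. Ggta1 was the one of these 8 values that stayed past the threshold whichever library was left out.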

How the results depend on the processing

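The alternatives chosen after seeing the data were total-read scaling, recomputed median-of-ratios factors and the block of pools matched from the data, and the alternatives to the added comparison of pre-mRNA with mRNA. A planned DESeq2 Wald test was not run, although whole reads were recovered. Of tests on the recovered reads only limma-voom was run. Of 254 named values past the threshold, none changed direction under any alternative. Of these values 129 dropped below the threshold without at least 1 library, 85 in fits of the compared groups only, 19 with total-read scaling, 14 with a pseudocount of 0.1, 9 with limma-voom, 4 with a limit of 1 on the log2 change, 1 with a pseudocount of 5, 1 with a mean of at least 5, and none with TMM scaling, recomputed factors, no filter or the block. With a mean of at least 1 read per 1000000, none of the 250 such values tested dropped. Median, mean and test differed in sign in 23 of 160 list tests, 0 of which passed at the preset correlation. The difference of the pre-mRNA and mRNA changes was not run with limma-voom, with the compared groups only or with the block. Fits without 1 library assume that the lone library of its group varies like the other groups. Averaged over genes, the variance between the 2 libraries of a group was 63.5 to 302 times that of counting. The most-read genes dominate this average, so depth limited little among them, and the average does not describe genes with few reads. The cause of each move below was not tested, beyond the fewer libraries of the smaller fits.

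A fit of the compared groups only called 83 genes by mRNA and 289 by pre-mRNA for IL-10 throughout against LPS, 32 by pre-mRNA for late IL-10, and 0 by mRNA (1382 at an unadjusted p under 0.05) and 19 by pre-mRNA between the schedules. It gave 33 (mRNA) and 155 (pre-mRNA) LPS-raised genes lower with IL-10 throughout and 20 pre-mRNAs higher with both schedules. The columns carry no replicate number, so libraries could not be paired by label. The fit that comes nearest to a paired one uses pools matched from the data. The replicate block of pools matched from the data takes its orientation from the values, so its p-values can be too small, by an amount that was not tested. The libraries so matched correlated at 0.35 to 0.89 by mRNA and 0.34 to 0.80 by pre-mRNA. Of named values that had not passed, 18 did with this block. With this block 6894 genes passed by mRNA for LPS, 1743 for IL-10 throughout, 6 for late IL-10 and 1562 between the schedules, and by pre-mRNA 2798, 478 and 2653 for the last 3. It gave 852 (mRNA) and 1364 (pre-mRNA) LPS-raised genes lower with IL-10 throughout, 213 pre-mRNAs higher with both schedules, and 2761 and 3473 (mRNA) and 2532 and 3212 (pre-mRNA) LPS-raised genes above untreated with IL-10 throughout and late IL-10. The block turned the mRNA split of IL-10 throughout to 685 rises and 1058 falls (39.3% rising in place of 53.1%). A pseudocount of 5 gave 139 and 141 there, and total-read scaling gave 89 higher and 69 lower between the schedules by mRNA in place of 59 and 65. The LPS split by pre-mRNA, 2484 to 2418, turned to 2340 and 2558 with TMM scaling and 2006 and 2132 in the fit of the compared groups. Total-read scaling gave 3 genes by mRNA for late IL-10, 826 and 1152 (mRNA) and 797 and 1079 (pre-mRNA) LPS-raised genes above untreated, and 88, 9 and 30 genes with different pre-mRNA and mRNA changes for LPS, late IL-10 and between the schedules. It turned the direction of 7 values that had not passed: Il4ra with LPS became -0.45 by mRNA and -0.13 by pre-mRNA, Bcl3 with LPS -0.48 by pre-mRNA, Cxcl10 with late IL-10 0.0027 by pre-mRNA, and between the schedules Ptgs2 0.23 by mRNA, Tnf 0.13 and Il4ra 0.0582 by pre-mRNA.

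With an estimated inter-gene correlation 0 lists passed in any comparison by either measure. By fry, which tests whether a list moves on balance and not against other genes, 4 lists passed by mRNA for IL-10 throughout, 1 by mRNA and 1 by pre-mRNA for late IL-10, and 3 by mRNA between the schedules. For late IL-10 by pre-mRNA, 5 lists passed at the preset correlation, 8 with limma-voom, 8 in the fit of the compared groups and 3 with the block.

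Leaving out each library in turn gave 1860 (without LPS B) to 3823 genes by mRNA and 3146 to 4834 by pre-mRNA for LPS, 43 to 192 and 62 to 1152 for IL-10 throughout, 29 to 87 by pre-mRNA for late IL-10, and 1 to 105 and 1 to 599 between the schedules. LPS-raised genes lower with IL-10 throughout ranged from 15 to 78 by mRNA and 26 to 612 by pre-mRNA, and pre-mRNAs higher with both schedules from 20 to 57. LPS-raised genes above untreated ranged from 744 to 1274 (mRNA) and 673 to 1336 (pre-mRNA) with IL-10 throughout, and from 1151 to 1911 and 1306 to 2106 with late IL-10. Genes with different pre-mRNA and mRNA changes ranged from 35 to 113 for LPS, 0 to 4 for IL-10 throughout, 0 to 10 for late IL-10 and 0 to 51 between the schedules. The covariance of the schedules' changes ranged from -0.0115 (without library B of late IL-10) to 0.276 by mRNA and from 0.111 to 0.643 by pre-mRNA. Lists called for late IL-10 ranged from 3 to 11 by mRNA and 3 to 8 by pre-mRNA, and the cytokine list's adjusted p by mRNA from 3.9e-07 to 0.28, the latter in the other direction.

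Values that had not passed and that changed direction without 1 library had these ranges. By mRNA, Il4ra with LPS ranged from -0.0368 to 0.63 and Ptgs2 from -0.40 to 0.80 with IL-10 throughout and -0.65 to 0.56 between the schedules. With late IL-10 by mRNA, Il6 ranged from -1.47 to 0.60, Il1b from -0.70 to 0.49, Il12b from -1.01 to 0.48, Cxcl10 from -0.57 to 0.75, Ifit1 from -0.90 to 1.05, Nos2 from -0.31 to 0.86, Ptgs2 from -0.17 to 0.67 and Il1rn from -0.23 to 1.62. By pre-mRNA, Ptgs2 with IL-10 throughout ranged from -0.13 to 1.12, and with late IL-10 Il1b ranged from -0.69 to 0.24, Cxcl10 from -0.49 to 0.44, Ifit1 from -0.85 to 0.62 and Ptgs2 from -0.033 to 0.93. Between the schedules by pre-mRNA, Nos2 ranged from -0.49 to 0.69 and Ptgs2 from -0.57 to 0.67.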

Other observations

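Both tests of the interferon-stimulated genes below, and the tests of library scaling and matched pools for late IL-10, were chosen only after the result was seen. Several genes that the comparisons above did not describe also changed by pre-mRNA, and those named here were chosen after their values were seen. With LPS the scavenger receptor gene Marco rose by 10.63 ± 0.75, the early activation antigen Cd69 by 8.66 ± 0.42, H2-Ab1, an MHC class II chain, by 3.49 ± 0.57 and the glycolytic gene Pfkl by 3.24 ± 0.20, while the transferrin gene Trf fell by 7.94 (SE 1.33), Cyp27a1, a sterol hydroxylase, fell by 4.03 (SE 0.43) and E2f1 fell by 3.18 (SE 0.42). Of 28 cell cycle genes 3 rose and 6 fell by pre-mRNA with LPS (2 and 4 adjusted over the list alone, list test adjusted p = 0.25), with Mki67 up by 3.40 ± 0.23. With IL-10 throughout, Lpl, lipoprotein lipase, fell by 2.55 (SE 0.32), Abcg1, a cholesterol exporter, fell by 1.98 (SE 0.31) and the lysosomal lipase gene Lipa fell by 1.64 (SE 0.21), while the lysosomal protease gene Ctsa rose by 3.08 ± 0.44. Ctsa overlaps Neurl2 in the annotation, so its rise and that of Neurl2 may share reads. Cd69 fell by 3.74 (SE 0.42), and Pkm, pyruvate kinase, rose by 2.05 ± 0.30.

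With late IL-10, 109 pre-mRNAs rose and 7 fell, a split that depended on the fit. At an unadjusted p under 0.05, 554 were higher and 293 lower. The block of pools matched from the data, whose p-values can be too small, gave 334 rises and 144 falls (69.9% rising in place of 94%). In the fit without a block, a bias of library scaling would have to shift all changes by 0.51 to give no more rises than falls, while the scalings differed by at most 0.027. Rises made 89.8% of the 59 calls among genes in the upper part of the LPS pre-mRNA range, split at its median, which argues against falls being hidden by a low starting level as the whole account. Falls that were under way and had not passed the threshold cannot be told apart from no change: of the genes lower with IL-10 throughout when LPS library B was held out, 31.2% of 753 were lower with late IL-10 than in that library (56.6% in the late IL-10 library of its matched pool, and 51.2% and 53.2% of all genes), and with LPS library A held out 91.7% of 72 were (93.1%, and 54.7% and 56.6% of all genes). A biological explanation, that IL-10 may raise transcription of its targets before it lowers that of inflammatory genes, stays open and was not tested.

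The 2 libraries of each LPS-treated group differed in interferon-stimulated genes, with 1 library higher in the list median by 1.29 to 1.43 by mRNA. Library scaling moves all genes of a library alike, and the list stood at least 0.943 above the median of all genes in the 3 LPS-treated groups, both measures and 3 scalings. An unequal split of reads between mRNA and pre-mRNA, with the pairing of their libraries unknown, cannot be told apart from a difference in RNA. Summed over both measures the list differed by 0.381 to 1.36 over both pairings, and the untreated libraries differed by 0.178 to 0.303. A split alone needed under 0.2, which no pairing gave, and at least 0.5 throughout would have argued against it. In libraries matched across groups, the differences between the sets by mRNA and by pre-mRNA correlated at -0.64 to -0.50 over 9515 genes. Sets named in reverse between the measures or a split would each give a negative sign, so this does not decide the pairing. The difference between libraries was not particular to this list. By mRNA the cell cycle list differed by 0.937 to 1.21 in the LPS-treated groups against 0.0859 untreated, and the costimulatory list by 0.824 to 0.913 against 0.0628. The IL-10/STAT3 list differed by 0.0937 to 0.245 against 0.226. The design names 2 independent macrophage pools, so a difference between pools, not only in the interferon response, may underlie the pattern. In libraries matched across groups (correlations of 0.66 to 0.89 among the LPS-treated groups) the interferon list was higher in the same set of libraries in all 3 groups by each measure. That match came from the same data and used these genes too, and libraries prepared in separate batches would look alike, so the explanation stays open.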
